A study of Mus musculus with 4 samples.

How the data were processed

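Gene expression was measured in mouse brain cortex with 1 library per group, each from RNA pooled over 4 animals, per the labels. The groups were wildtype baseline, wildtype sleep-deprived, knockout baseline and knockout sleep-deprived, so that 4 libraries held 16 animals in a 2 by 2 design without replicates. Sleep deprivation lasted 4 h by gentle handling from light onset, per the labels. RNA was extracted with a column kit and treated with DNase, and sequencing was on a HiSeq2500. The read aligner and the part each step played in the deposited tables are not given in the sources used here, beyond the submitters' processing notes, which name RSEM 1.2.19 for counting and edgeR for the comparisons.

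Each of the 4 comparisons had its own deposited table, with 39179 genes and the values of all 4 libraries. The expression signal, per the file headers and values, is an estimated count per gene that the authors divided by 1 factor per library. The log2 ratios in the same tables are the authors' values for each comparison, deposited as baseline over sleep deprivation or wildtype over knockout, and were turned round here. The p-values and FDR values in the authors' deposited tables were made from single libraries and are quoted only as the authors' counts. The GC fraction of each gene is as deposited by the authors. The transcript width in bp is also as deposited by the authors. No cell differed between the tables in the values of the libraries, and 14 gene symbols turned into dates were matched by identifier.

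The plan, made before the data were examined, assumed raw counts. The files hold normalised values that are not whole numbers, so limma 3.58.1 was run on log2 values in place of count models. The comparisons, the filter, the 1.5-fold threshold, the 31 gene lists, the rule for naming genes and most alternatives were also set before the data were examined. The factor of each library was estimated from its lowest values, where 1 read equals 1.15 normalised counts in WT BL, 1.11 in WT SD, 1.25 in KO BL and 0.878 in KO SD. Dividing each value by this factor gave an estimated read count and from it exact binomial 95% intervals that cover counting error alone, not the difference between animals or libraries. A floor of 3 reads corresponds to 3.44, 3.33, 3.76 and 2.63 normalised counts. Of the genes, 19106, 19154, 19105 and 18467 were listed at 0 in the respective libraries. Mitochondrial transcripts made up 13.4%, 13.5%, 12.7% and 19.4% of normalised counts.

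Fold changes were log2 of the deposited value plus 1, for genes with a mean of at least 50 normalised counts. Genes at least 1.5-fold different were counted, and a difference of responses was counted from 1 on the log2 scale. Shared changes were counted between pairs without a common library and set beside the product of the separate shares. The correction was a loess fit (span 0.3, degree 2, symmetric) of each library minus the mean of all 4 on GC content and log10 length, a version per library of the fit per comparison that was planned. The correction also centres each library. It was planned as an alternative and is printed beside the main values because of the trends found. The additive model was fitted with limma (trend variance) on 4 libraries with 1 residual degree of freedom. At deposited values the prior degrees of freedom were infinite, so that each gene took its variance from the trend, and at corrected values they were 6.28. A list's median was placed among 10000 random lists drawn from 20 bins of mean expression, and 618 of the 620 genes in the lists were found in the tables.

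The rule for naming took Kcnma1 and, in each comparison, the 10 protein-coding genes most raised and the 10 most lowered past 1.5-fold. For each shared change it took 10 per direction by the smaller fold, for the difference of responses 5 per direction, and from each list up to 4 members with the largest folds and any needed for a range. Gene models named Gm or Rik were counted and passed over, except where a model called few genes. Exon overlap was taken from GENCODE M21: 4086 of the genes compared share an exon with another gene, 119 have a repeated symbol, 47 are listed at 0 in a library and 160 have no exons in that annotation, so that overlap was not found for them. Because such genes filled the extremes, a second naming on corrected values without them was added after the values were seen. Coordinates are 1-based on mm10 (GRCm38).

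The procedure was tested on simulated data with 200 changed genes and noise of SD 0.2. Of genes changed 2-fold, 84.0% were found past 1.5-fold in both pairs after the correction, with 0.187% of other genes, against 56.0% and 1.59% without it. The simulated noise was equal in all libraries. In the corrected data the median absolute deviation from the mean of the others was 0.377 in WT SD and 0.191 to 0.231 in the rest. The wildtype pair holds WT SD, so the simulated shares for both pairs may be too favourable. The simulated trends were those that the same correction had fitted to the data. Its gain over uncorrected values was therefore largely fixed beforehand. Software was R 4.3.3 with data.table (version 1.17.8) and limma. Alternatives were scaling by total counts and by median of ratios, other filters, a smaller pseudocount, a 2-fold threshold, protein-coding genes alone, the authors' ratios, corrections for GC content, length or both, lists matched on length, a 10 Mb window around Kcnma1, and sets without ambiguous genes or without the library WT SD. Other count models and precision weights from counts were left out, as the values are not counts. The leptomeninges list, not among the 31, was chosen after its members' values were seen. A few genes that the naming rule or the lists would have given are not reported here.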

Results

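RNA from brain cortex was compared between mice lacking the BK channel, a potassium channel of large conductance opened by calcium and depolarisation, and their wildtype littermates. All animals were F1 offspring of C57Bl6/J and Sv129 parents. In each genotype, animals were either kept awake for 4 h from light onset or left undisturbed, and all tissue was taken at the same clock time (ZT4). Total RNA was sequenced as 4 libraries, each from a pool of 4 animals: wildtype baseline (WT BL), wildtype sleep-deprived (WT SD), knockout baseline (KO BL) and knockout sleep-deprived (KO SD). Each group thus had 1 library and no replicate. The deposited values summed to 34.5 M normalised counts in WT BL, 38.7 M in WT SD, 34.7 M in KO BL and 36.9 M in KO SD. The corresponding estimated reads were 30.1 M, 34.9 M, 27.7 M and 42.0 M. Of 39179 annotated genes, 13550 had a mean of at least 50 normalised counts over the 4 libraries and were compared, and 12866 of these were protein-coding. A gene was counted as higher or lower at 1.5-fold, and fold changes are given on the log2 scale. A corrected value is one from which trends with GC content and transcript length were removed.

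Kcnma1 (ENSMUSG00000063142, mm10 chromosome 14, 23289431 to 23803304), which codes for the pore-forming subunit of the BK channel, was read in all 4 libraries. Its value was 614 normalised counts in WT BL (95% counting interval 563 to 668), 177 in WT SD (151 to 208), 447 in KO BL (402 to 496) and 491 in KO SD (451 to 533). The log2 difference of KO over WT was -0.46 at baseline (-0.66 to -0.26) and -0.14 after the correction. After sleep deprivation the same difference was 1.46 (1.21 to 1.73) and 1.02 after the correction. The values of Kcnma1 therefore did not separate the genotypes, and the labels do not say which part of the gene was deleted. Genotypes are named here as the labels give them.

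The libraries differed along GC content and transcript length, and whole gene groups moved with these properties. In the shortest 1355 genes, with a median length of 754 bp, the median fold of WT SD over WT BL was 1.19, and in the longest 1355 (5615 bp) it was -0.54. When both fitted trends were subtracted, the median of ribosomal protein genes in this pair went from 2.12 to 1.10, and that of genes of GABA signalling from -0.63 to -0.34. The shortest 1355 genes kept a corrected median of 0.17 in this pair and of -0.14 for KO SD over WT SD. Corrected medians of lists of short genes may thus hold part of the length trend. Across genes, the rank correlation of fold with GC content was 0.33 for sleep deprivation in wildtype pools and -0.71 in knockout pools. For the genotypes it was 0.80 at baseline and -0.38 after sleep deprivation. WT SD also stood apart from the other libraries across genes, with correlations of 0.877 to 0.911 against 0.956 to 0.972 among the other 3. Mitochondrial 16S ribosomal RNA (mt-Rnr2) was at 204600 normalised counts in WT BL, 768700 in WT SD, 189000 in KO BL and 482900 in KO SD.

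**Figure D1:**
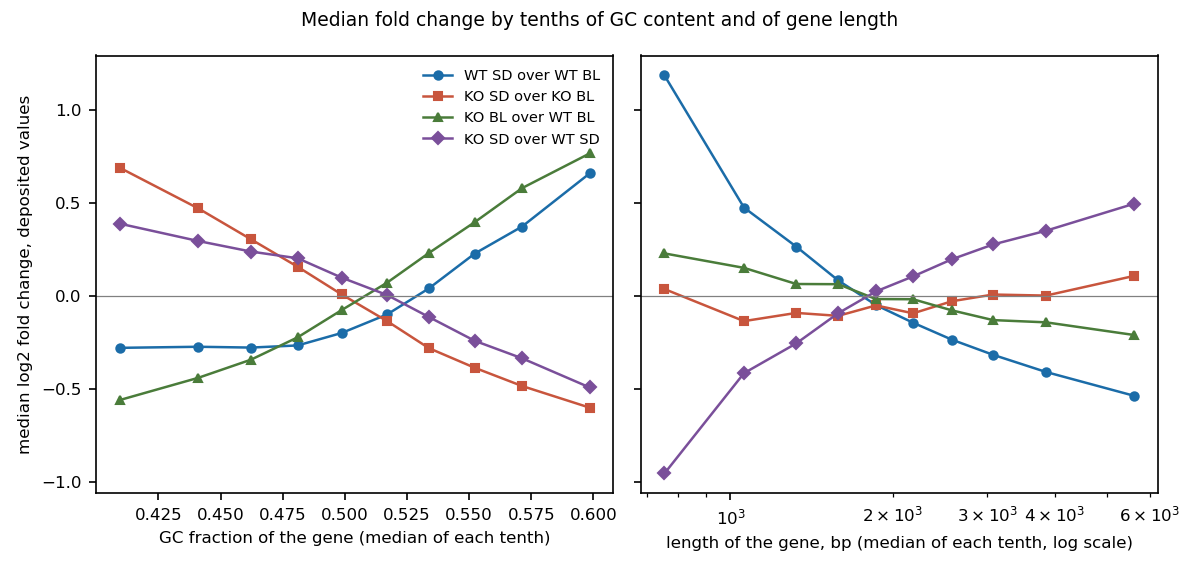
Median log2 fold change (deposited values) in 10 equal bins of genes by GC fraction (left) and by transcript length in bp (right, log scale); each line is 1 of the 4 comparisons. In the bin of highest GC content the median was 0.66 for sleep deprivation in wildtype pools and -0.60 in knockout pools.

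The first comparison asked what sleep deprivation changed in wildtype cortex (WT SD over WT BL). Transcripts switched on by neuronal activity were higher in WT SD. Nr4a2 and Nr4a3, nuclear receptors of the immediate-early class, stood at 968 and 1473 normalised counts against 239 and 406 in WT BL. Arc, whose RNA travels to active synapses, stood at 11010 against 4207, and Fosb, a subunit of the AP-1 transcription factor, at 1003 against 326. Transcripts of ribosomal proteins and of the nuclear-encoded respiratory chain were higher as groups, those encoded by mitochondria lower, and the median GABA signalling gene was lower. In all, 3321 genes were higher and 3259 lower, 48.6% of those compared. Scaling by total counts, which moved the median of all genes from -0.04 to -0.21, gave 38.4% of them as higher in place of 50.5%. After the correction 2503 were higher and 2464 lower, and 3717 of the original genes kept their direction and size. With 1 library per group, the difference has no replicate check. In the authors' deposited table, 513 genes were higher and 398 lower at an adjusted p under 0.05, computed without replicates.

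The extremes of this comparison held genes that were all but missing from 1 library. Eif4ebp3, a repressor of translation, and the homeobox gene Hoxd9 were listed at 0 in WT BL and at 230.2 and 229.7 in WT SD. Mier2 was listed at 0 in every library but WT SD, under a symbol that another identifier shares. Hoxd8, next to Hoxd9, was 6.01 higher (4.40 to 12.22 by counting), from 1.15 to 138. Mrpl23, a protein of the mitochondrial ribosome, was 5.96 higher, Tom1, an endosomal adaptor listed at 0 in KO SD, 4.55, and Rpl36 4.06. Gp1bb, Pcsk1n and Lrrc17 were 5.12, 4.05 and 3.96 higher, but share exons with neighbouring genes. Srp54a of the signal recognition particle, Snurf from the imprinted Snrpn locus and the mitochondrial carrier Slc25a30 were listed at 0 in WT SD only, after 2563, 603 and 72.3 in WT BL. Adnp and Ugt1a6a were also listed at 0 there and share exons, as do Moap1, Fam120c, Palm2Akap2 and Irs2, which were lower by values from -6.49 (Moap1) to -5.71 (Irs2). Lyst, a regulator of lysosome size, stood at 16.7 against 787 (-5.48).

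Among genes with no shared exon, a unique symbol and no library at 0, a choice made after the values were seen, those most lowered by corrected values in WT SD were Ccdc85c (-5.61) and Cuedc1 (-5.59). Of others among the 10 lowest, the serotonin receptor Htr2a stood at 3.40 against 180.2 in WT BL (corrected -4.87), the muscarinic receptor Chrm3 at 38.9 against 1233 (-4.86) and the somatostatin receptor Sstr1 at 3.33 against 137 (-5.45). The volume-regulated channel subunit Lrrc8b (-5.03) and Gpam of triglyceride synthesis (-4.78) were about as low. In KO SD these genes stood at 174 (Htr2a), 494 (Chrm3), 101 (Sstr1), 462 (Lrrc8b) and 823 (Gpam). The genes most raised by corrected values, after Hoxd8 and Mrpl23, included Ndufb7 of respiratory complex I (3.12), the zinc-finger gene Zfp352 (3.11), the protease inhibitor Cst6 (3.01) and the helicase Brip1 (2.78).

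Of 37 activity-regulated early genes, 22 were higher and 2 lower in WT SD, with a median of 0.84. As a description of these libraries, list medians were placed among 10000 random lists of like expression, and this one lay at percentile 100, as did its corrected median of 0.91. Gadd45g (2.41), Egr4 (2.32), Maff (2.26) and Junb (2.09) led the list. The exceptions were Egr3, a zinc-finger factor of the same class, at 18.9 against 413, and the kinase Pim1 (-0.78), which shares exons. Of 23 glucocorticoid-responsive genes 11 were higher and 7 lower, with a median of 0.46 at percentile 98.6 (corrected 0.29, percentile 95.6). The metallothioneins Mt1 (3.10) and Mt2 (3.15), the anti-inflammatory factor Tsc22d3 (1.85) and the cell cycle inhibitor Cdkn1a (1.87) were higher, and Klf9 (-1.94) and Zbtb16 (-1.78) lower. Among 24 cytosolic heat shock genes 7 were higher, led by Hspb1 (2.67) and Hspe1 (1.83), and 1 was lower, Hspa4l (-0.69), with a median of 0.35 at percentile 95.4. Of 21 chaperones and unfolded-protein genes of the endoplasmic reticulum, 6 were higher and 3 lower around a median of 0.24 (percentile 86.1). There Ddit3 (2.21), Sdf2l1 (2.08) and Creld2 (1.92) were higher and the chaperone Hyou1 lower (-1.17).

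Of 23 clock genes 3 were higher and 5 lower in WT SD, with a median of -0.20 at percentile 16.3. The repressors Per1 (0.69) and Cry1 (0.68) were higher and the output factors Hlf (-1.03) and Per3 (-0.89) lower. The list of 4 cold-inducible RNA-binding genes also held Rtn2, a reticulon of the endoplasmic reticulum, which alone was higher (1.38), while Cirbp stood at -0.04 (list median 0.21, percentile 68.8).

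Genes of excitability had medians under 0 in WT SD. Of 37 potassium channel genes 14 were lower and 4 higher, with a median of -0.37 at percentile 0.875. The delayed rectifier Kcna2 (-4.95) and the G-protein-gated Kcnj6 (-2.80) were lowest, and Kcnmb4, the neuronal BK auxiliary subunit, was 1.42 higher. Of 47 calcium genes 20 were lower and 4 higher (median -0.40, percentile 0.06), among them the R-type channel Cacna1e (-4.48) and the exchanger Slc8a1 (-3.14), while the kinase Camk1 was higher (1.02). Of 38 glutamate receptor and scaffold genes 15 were lower and 6 higher (median -0.39, percentile 0.52). The scaffold Dlg2 stood at 367 against 5173, and the NMDA receptor subunit Grin2a was also lower (-2.51). Of 21 genes of the GABA list 12 were lower and 2 higher (median -0.63, percentile 0.02), with the receptor subunit Gabrb2 at -3.75 and its sister Gabrb1 at 1.83. The corrected medians of these 4 lists were -0.20, -0.21, -0.20 and -0.34, at percentiles 2.18, 0.84, 2.12 and 0.74. Against random lists matched on length as well as expression, the deposited medians lay at percentiles 19.4, 7.82, 29.9 and 0.50.

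All 51 ribosomal protein genes compared were higher in WT SD, by a median of 2.12 at percentile 100. Rps21 stood at 23480 against 2003, Rpl28 was 3.20 higher and Rps15 3.19 higher. After the correction the median was 1.10, still at percentile 100, with 43 higher. Of 38 nuclear-encoded genes of oxidative phosphorylation 29 were higher, led by Ndufa2 (3.42) and Uqcrq (3.13), with a median of 1.31 that became 0.35 after the correction (percentile 99.1). The 13 mitochondrially encoded transcripts went the other way, with 7 lower and 3 higher (median -0.59, percentile 0.145; corrected -0.90, percentile 0). There mt-Atp8 stood at 7163 against 93140 and mt-Nd5 at 30380 against 159200, while mt-Nd3 was 1.37 higher. Of 28 genes of glucose, glycogen and lactate metabolism 10 were higher and 3 lower, with Ldhb (1.10) and Pfkl (0.97) among the highest and Pgam1 lowest (-1.05). Their median of 0.45 lay at percentile 98.4 (94.0 against lists matched on length), and the corrected median of 0.03 at 43.6. Of 25 genes regulating protein synthesis 4 were higher and 5 lower (median -0.21, percentile 13.8), from Eif4ebp2 (-3.15) to Ddit4 (0.69). Of 24 cholesterol genes 6 were higher, such as Pmvk (1.46), and 5 lower, such as Stard4 (-1.65), around a median of 0.05 (percentile 62.6). Of 18 interferon-response genes 5 were higher and 7 lower, from Gbp2 (-2.08) to Bst2 (1.39), with a median of -0.13 (percentile 40.9).

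Among marker lists, microglial genes were higher in WT SD, 7 of 12 with none lower and a median of 0.67 (percentile 99.2, or 97.3 against lists matched on length), led by Aif1 (2.21) and the complement gene C1qa (1.69). Oligodendrocyte markers were higher in 5 of 12, such as the myelin genes Mbp (1.08) and Mobp (0.82), with a median of 0.53 (percentile 96.8). Precursor markers held 3 higher and 1 lower of 8 (median 0.31, percentile 84.6), with Pdgfra at -1.12. Astrocyte markers held 4 higher and 2 lower of 12 (0.34, percentile 86.9), from Sox9 (1.35) to Aqp4 (-1.01). Excitatory neuron markers held 5 higher and 1 lower of 11 (0.11, percentile 66.0), with Foxp2 (1.66) and the calmodulin-binding Nrgn (1.44) among the higher. Inhibitory neuron markers held 4 higher and 2 lower of 12 (-0.17, percentile 27.4), from Pvalb (2.08) to Dlx2 (-0.80). Striatal markers held 3 higher and 2 lower of 9 (0.43, percentile 90.5), from Tac1 (2.19) to Pde10a (-1.76). Of 5 hippocampal markers 3 were lower, Dgkh most (-1.77), with a median of -1.39 (percentile 0.50) that became -0.80 after the correction (percentile 3.58). Of 5 thalamic markers Tcf7l2 was higher (0.92), with a list median of -0.03 (percentile 51.8).

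Vessel and blood markers were mixed in the same pair. Endothelial markers held 5 lower and 1 higher of 10 (median -0.58, percentile 2.08, or 4.76 against lists matched on length; corrected -0.22, percentile 13.8), from Cdh5 (-1.56) to the tight-junction gene Cldn5 (1.70). Markers of pericytes, smooth muscle and meninges held 4 lower of 12 (-0.22, percentile 28.8), with the matrix genes Dcn (-1.36) and Lum (-1.19) lowest. Of 4 choroid plexus and ependyma markers 2 were lower, such as Kl (-1.31), and 1 higher, Foxj1 (0.93; list median -0.64, percentile 19.1). Of 5 red blood cell genes 2 were lower and 1 higher (-0.53, percentile 6.98), and after the correction all 5 were lower with a median of -2.14 (percentile 0). Xist, the only sex-chromosome marker compared, differed by -0.12. Of the genes named here from lists, Junb, Hspe1, Ddit3, Kcnmb4, Slc8a1, Camk1, Gabrb1, Rpl28, Ndufa2, mt-Atp8, mt-Nd5, Gbp2, Pdgfra and Xist overlap exons of other genes, so that their reads are less surely assigned.

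The second comparison put the same question to the knockout pools (KO SD over KO BL). The immediate-early receptors Nr4a2 and Nr4a3 were again higher, at 1635 against 367 and 1452 against 484. Homer1, whose short activity-induced form loosens synaptic scaffolds, stood at 15300 against 4051 (1.92, 1.86 to 1.97 by counting), and the prostaglandin synthase Ptgs2 was 1.59 higher. Astrocyte genes for glutamate uptake were higher, Slc1a2 by 0.99 and Slc1a3 by 0.82, and genes of red blood cells were lower. In all, 2193 genes were higher and 2225 lower, 32.6% of those compared; scaling by total counts gave 37.7% of them as higher in place of 49.6%. After the correction 1055 were higher and 723 lower, and 1163 of the original genes kept their direction and size. The difference again rests on 1 library per group. The authors' deposited table gave 21 genes as higher and 20 as lower at an adjusted p under 0.05.

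The gene most raised without a repeated symbol was Ttr, the thyroid hormone carrier made in the choroid plexus, at 581 in KO SD against 65.0 in KO BL. Scn7a, a sodium channel that senses sodium level, was 2.34 higher, Luzp2 2.17, and Rpe65, an enzyme of the visual cycle, 1.85. Rps16 was 1.85 higher, from 150 to 542, far under its 909 in WT BL. Dio2, which activates thyroid hormone in astrocytes, was 2.15 higher and Lenep 2.96, and both share exons with other genes. Both extremes under the symbol Sowahc belong to a pair of identifiers and could not be assigned to a gene. Lowest were Hfe2, an iron regulator (-2.37), Lars2, a mitochondrial tRNA synthetase (10590 against 53160), and Lbp, which binds bacterial lipid (-2.24). Haemoglobin and haem genes were also among the lowest, with Hbb-bt and Hba-a1 both at -2.10 and Alas2, which shares exons, at -2.26. Slc47a1, an exporter of organic cations, followed (-2.09). Tom1 was listed at 0 in KO SD, and Yjefn3 (-2.22) shares exons.

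Of 37 early genes 12 were higher and 2 lower in KO SD, with a median of 0.28 at percentile 98.9, and after the correction 19 were higher around a median of 0.75 (percentile 100). Junb was lower (-1.42), opposite to its value in WT SD. Chaperones of the endoplasmic reticulum were higher in 10 of 21 and lower in 1 (median 0.41, percentile 99.4; corrected 0.24, percentile 98.6), with Dnajb9 at 1.04 and the master chaperone Hspa5 at 0.96. Of 23 glucocorticoid-responsive genes 5 were higher and 2 lower (0.22, percentile 92.8; corrected 0.38, percentile 100), with Tsc22d3 (1.13) and the metabolic switch Pdk4 (1.08) highest. Heat shock genes were centred at 0.00 (3 higher, 1 lower of 24, percentile 54.3), with Chordc1 at 0.98. Clock genes were mixed, 6 higher and 4 lower of 23 (0.08, percentile 73.9), with Nr1d1 (-1.36) and Ciart (-1.23) among the lower and Rorb (1.24) among the higher. Cold-inducible genes held Cirbp (-0.99) as lower (median -0.16, percentile 30.6; corrected -0.43, percentile 0.58, with none of 4 past 1.5-fold).

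The median glycolytic transcript was lower in KO SD. Of 28 genes of glucose, glycogen and lactate metabolism 11 were lower and 3 higher (median -0.34, percentile 1.17), and after the correction 2 were lower and 2 higher (-0.24, percentile 0.09). The lactate exporter Slc16a3 (-1.85) and Pfkl (-1.02) were lowest, and the glycogen-targeting subunit Ppp1r3c was highest (1.57). Calcium genes were lower in 15 of 47 and higher in 3 (-0.27, percentile 1.59; corrected -0.17, percentile 0.12), with the exchanger Slc8a2 (-1.24) and the AMPA receptor auxiliary subunit Cacng8 (-1.08) among the lowest. Regulators of protein synthesis held 7 lower and 5 higher of 25 (-0.46, percentile 0.13), from Eif4ebp1 (-1.35) to Eif4e (0.93), with a corrected median of -0.09 (percentile 12.6). Potassium channels (4 higher, 11 lower of 37, median -0.14), glutamate genes (6 higher, 10 lower of 38, -0.18) and GABA genes (7 higher, 2 lower of 21, 0.05) lay at percentiles 16.7, 7.47 and 65.5. The inward rectifier Kcnj4 (-1.37) and the receptor Grm2 (-1.57) were the lowest of these, and the subunit Gabrg1 (1.75) the highest GABA gene. Ribosomal proteins were higher in 11 of 51 and lower in 1, Rps6 (median 0.25, percentile 99.0). Nuclear-encoded oxidative phosphorylation was at 0.17 (4 higher, 1 lower of 38, percentile 91.0), cholesterol synthesis at -0.16 (6 higher, 6 lower of 24, percentile 21.3) and the interferon list at 0.08 (4 higher, none lower of 18, percentile 74.5). The mitochondrially encoded transcripts were higher in 5 of 13, such as mt-Co1 (1.06), with a median of 0.51 (percentile 99.2) that became -0.30 after the correction (percentile 0.88).

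Astrocyte markers were higher in 6 of 12 in KO SD (median 0.58, percentile 99.7; corrected 0.54, percentile 100), led by the water channel Aqp4 (1.35). Thalamic markers were higher in 3 of 5 (0.83, percentile 99.7), Rora most (0.94). All 5 red blood cell genes were lower (-2.10, percentile 0; corrected -1.75, percentile 0). The other medians of marker lists fixed beforehand lay between percentiles 8.37 and 76.2, with inhibitory neurons (-0.29) lowest in rank and endothelium (0.11) highest. Among them, after the correction, excitatory neurons (0.38, percentile 99.5) and microglia (0.29, percentile 99.1) ranked high, and pericytes, smooth muscle and meninges low (-0.28, percentile 1.38).

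**Figure D2:**
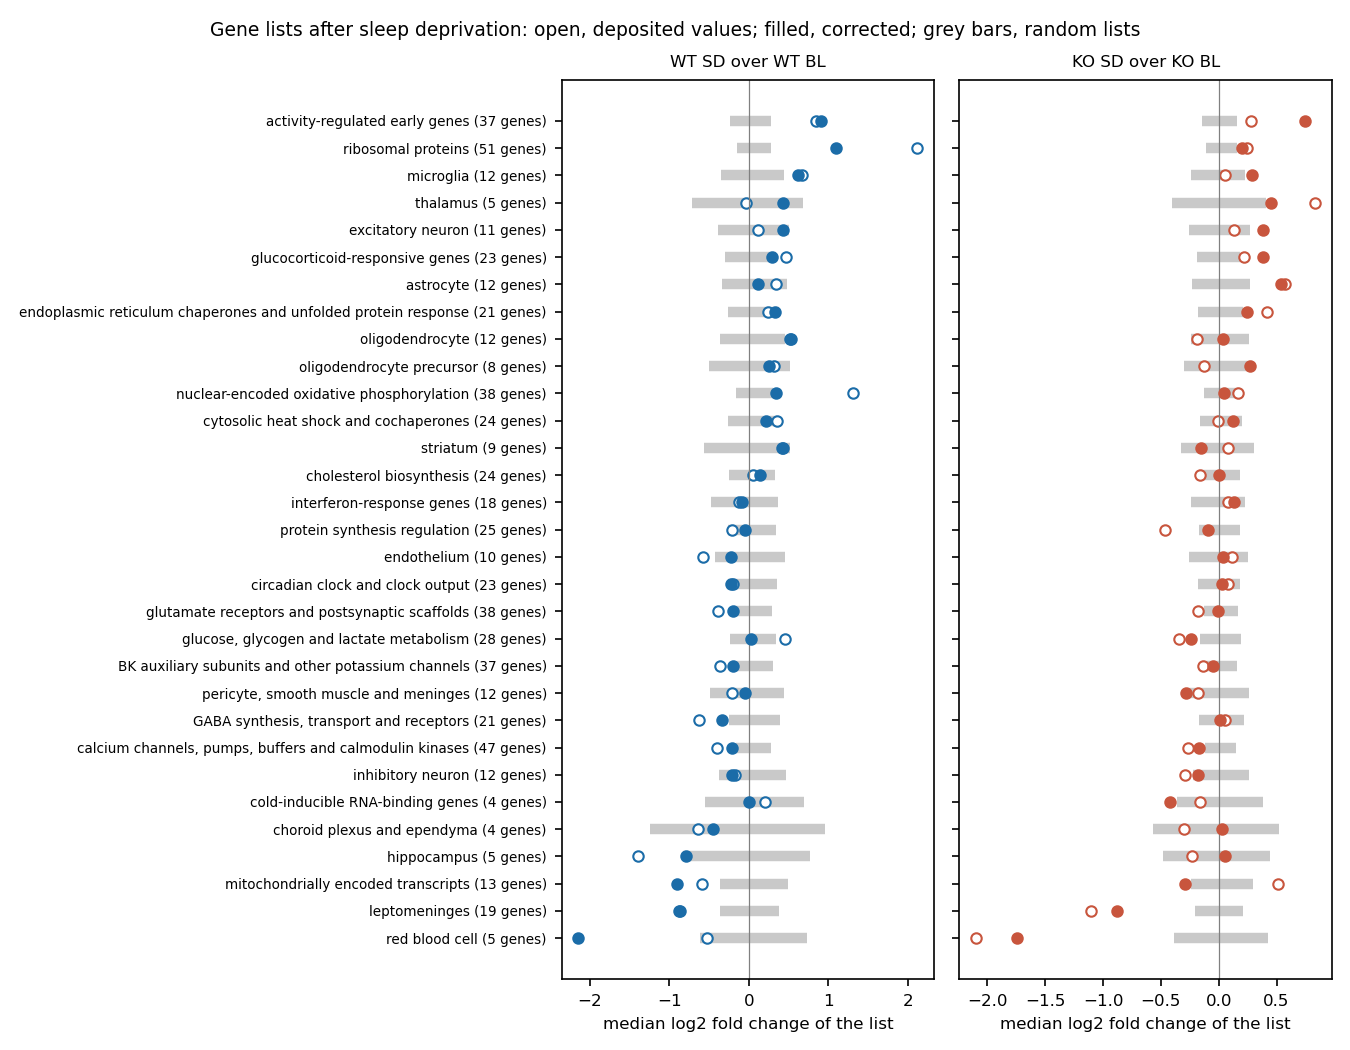
Median log2 fold change of each gene list after sleep deprivation in wildtype pools (left) and knockout pools (right); open points use deposited values, filled points corrected values, and grey bars span 2 SD either side of the median of random lists on corrected values. The early genes stood at 0.91 and 0.75 after the correction, and the leptomeninges list, chosen after the values were seen, at -0.87 and -0.88.

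Both pairs of libraries share no library, so genes past 1.5-fold the same way in both genotypes give the only repeated measure of sleep deprivation. The sleep-deprived libraries also held more mitochondrial ribosomal RNA, 3.33% of normalised counts in WT SD and 2.22% in KO SD. The baseline libraries held 1.02% (WT BL) and 0.932% (KO BL). Anything else that the sleep-deprived libraries had in common cannot be told apart from sleep deprivation by these shared changes. The orphan receptors Nr4a2 (2.01 in wildtype, 2.15 in knockout) and Nr4a3 (1.86 and 1.58) were higher in both. Ube3a, a ubiquitin ligase imprinted in neurons (1.64 and 1.65), the cGMP-dependent kinase Prkg2 (1.38 and 1.72), the endothelial trafficking gene Nostrin (1.35 and 1.63) and the hyaluronan-binding Tnfaip6 (1.33 and 1.40) were too. By the smaller fold Nr4a2 and then Rps16 (2.80 and 1.85) ranked first. Neuromedin B (Nmb, 2.90 and 1.62), Lrrc17 and Gngt2 met the rule but share exons. Lower in both were the cation exporter Slc47a1 (-2.60 and -2.09), the collagen Col8a2 (-1.70 and -1.86), the iron regulator Hfe2 (-1.61 and -2.37) and the adhesion genes Olfm2 (-1.73 and -1.58) and Cdh1 (-1.53 and -1.60). The KATP channel pore Kcnj11 was also lower (-3.02 and -1.52). Alas2, which makes haem in red cells (-2.60 and -2.26), Shisa3, Tnfsf12Tnfsf13 and Moap1 were lower and share exons.

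In number, the shared changes at deposited values and 1.5-fold were close to what chance gives, with 509 higher in both against 537 by the product of the separate shares and 563 lower against 535. At 2-fold, 202 were shared against 127 by chance. Without the filter on the mean 2774 were shared against 1549, a product lowered by genes without reads, which cannot pass. Scaling by total counts gave 27.9% of the shared changes at 1.5-fold as higher in place of 47.5%. After the correction 441 were higher in both against 195 by chance and 363 lower against 131. Among the 9340 genes with no shared exon, a unique symbol and no library at 0, the corrected counts were 303 against 137 and 245 against 89.5. Across genes, which are not independent replicates, the correlation of both folds went from 0.06 (Pearson) and -0.01 (Spearman) to 0.29 and 0.33 after the correction. By corrected values Maff, a small Maf factor (1.98 and 1.70), joined the genes most raised in both, as did Dio2 (1.76 and 1.69), Plekhg4 and the histone gene Hist2h3c1, the last 3 sharing exons. The clock repressor Per2 passed 1.5-fold in both pairs after the correction (0.92 and 0.99) but not in the wildtype pair before it (0.52), and Tsc22d3 was higher in both (corrected 1.91 and 1.16). Those most lowered by corrected values took in Hbb-bt (-2.14 and -2.19), the oxidase Aox3 (-1.92 and -1.85), Ripply2 (-1.71 and -1.73), Hbb-bs (-1.60 and -1.69) and the betaine transporter Slc6a12 (-1.70 and -1.46).

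**Figure D3:**
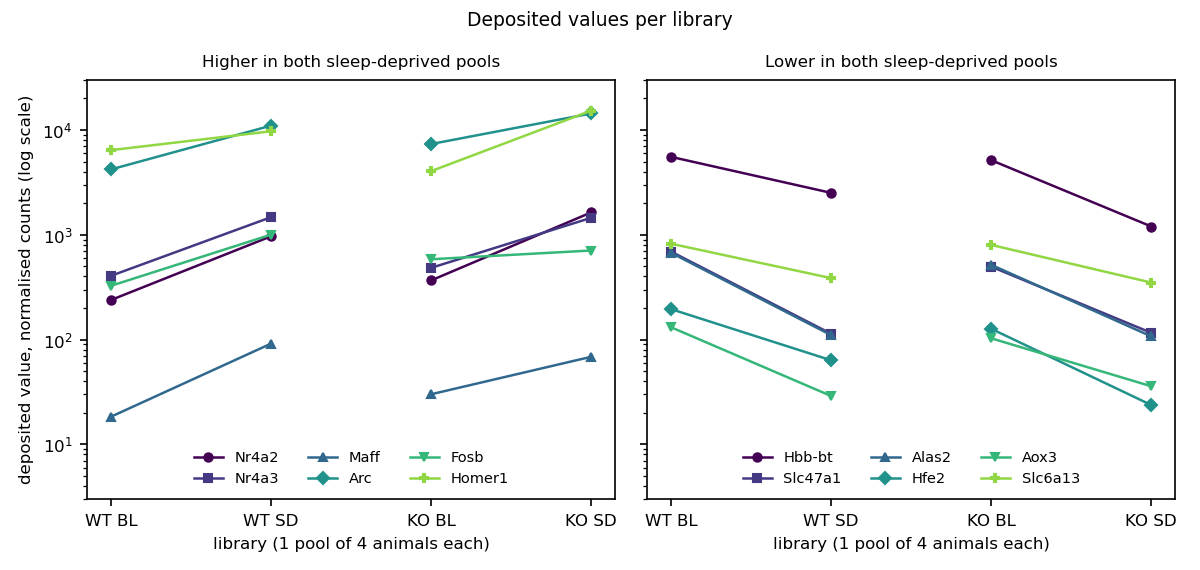
Deposited values (normalised counts, log scale) of 6 genes higher and 6 genes lower in both sleep-deprived pools; each point is 1 library and lines join the libraries of a genotype. Nr4a2 went from 239 to 968 in wildtype and from 367 to 1635 in knockout pools; Alas2, which shares exons with another gene, went from 672 to 110.0 and from 516 to 107.

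Transcripts typical of the leptomeninges, the thin membranes over the cortex, were lower in both sleep-deprived pools, by a list of 19 genes chosen after their values were seen. In wildtype pools 14 were lower and 2 higher (median -0.88, percentile 0), and in knockout pools 15 lower and none higher (-1.10, percentile 0). The solute carriers Slc6a13 (-1.09 and -1.19) and Slc22a6 (-1.11 and -1.11), the retinoic acid enzyme Aldh1a2 (-1.17 and -0.96) and the collagen Col3a1 (-1.51 and -0.97) were lower in both. Ptgds, the prostaglandin D synthase, was 0.63 higher in wildtype and lower in knockout pools (-1.29). The list of pericytes, smooth muscle and meninges fixed beforehand was not apart in wildtype pools (corrected median -0.04, percentile 46.4).

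The additive model of genotype and sleep deprivation (limma, 2 pools against 2) called 33 genes higher and 69 lower after sleep deprivation, at an adjusted p under 0.05. It called 45 higher and 7 lower in the knockout pools. At deposited values limma took each gene's variance from the trend alone, and 830 and 278 genes had an unadjusted p under 0.05 against 677.5 by chance. After the correction, where limma weighed 1 residual degree of freedom per gene with 6.28 from the trend, 3 genes were called for sleep deprivation and 1 for genotype, with 1581 and 385 at an unadjusted p under 0.05. The pseudogene Gm15487 was 4.15 higher after sleep deprivation (SE 0.25, adjusted p 0.00290), with 409 and 16260 normalised counts in the wildtype and 50.5 and 705 in the knockout libraries, and was also lower in the knockout pools (-3.56, adjusted p 0.0173). The gene model B930041F14Rik, whose symbol belongs to more than 1 identifier, was lower (-7.92, SE 0.47, adjusted p 0.00290), from 887 to 4.73 and from 1261 to 2.42. The pseudogene Gm13841 was also lower (-6.94, SE 0.44, adjusted p 0.00290), from 946.5 to 29.7 and from 702 to 2.63.

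The third comparison asked how the knockout differed from wildtype in undisturbed animals (KO BL over WT BL). Myelin transcripts were higher in KO BL, with Mbp, the myelin basic protein, at 28500 against 11790, Mag at 2366 against 1030 and Mobp at 5574 against 3061. Rps16 was lower, at 150 against 909, and so was Xaf1, which counters an inhibitor of apoptosis, at 170.3 against 450 (-1.40, -1.69 to -1.12 by counting). Lpl, which releases fatty acids from lipoproteins, was also lower (-0.89). In all, 2227 genes were higher and 1444 lower, 27.1% of those compared. After the correction 432 were higher and 471 lower, and 539 of the original genes kept their direction and size. As Kcnma1 did not separate the libraries, the direction rests on the labels, with no replicate. The authors' deposited table gave 17 genes as higher and 13 as lower at an adjusted p under 0.05.

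Several of the largest differences in this pair were again of genes missing from 1 library. Hoxd9 was listed at 0 in WT BL and stood at 119 in KO BL, and its neighbour Hoxd8 was 4.80 higher. Gdf1, a growth factor of the TGF-beta family, was listed at 0 in both knockout libraries, at 177 in WT BL and at 1026 in WT SD. It lies within Cers1, which went the other way (786 in WT BL, 2096 in KO BL), so reads of 1 gene may have been counted for the other. Zbtb20, under a repeated symbol, was at 0 in the same libraries. Mrpl23 (3.06), Erdr1 (2.82), the early-gene relative Ier5l (2.70) and the secreted C1qtnf4 (931 against 163) were higher, as were Tom1 (3.15), Plin4 (3.12, sharing exons) and Eif4ebp3, listed at 0 in WT BL. The photoreceptor cadherin Cdhr1 (-2.08), Samd15 (-1.55) and the sodium channel Scn7a (-1.53) were lower, as were Lenep (-2.57) and Nanp (-1.75), which share exons, and Fam220a (-2.30), whose symbol is repeated. By corrected values and among genes without these ambiguities, the glycogen adaptor Stbd1 (2.06), the synaptic organiser Cbln1 (1.99), Rps7 (1.95), the thyrotropin-releasing hormone receptor Trhr (1.91) and the kappa opioid receptor Oprk1 (1.60) were among the highest, after Hoxd8 and Mrpl23. Klf5 (-1.59) and the neuroendocrine factor Insm1 (-1.44) were among the lowest, after Rps16 and Cdhr1.

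Oligodendrocyte markers were higher in 6 of 12 in KO BL with none lower (median 0.59, percentile 99.9), and in 8 of 12 after the correction (0.66, percentile 100). This was not repeated after sleep deprivation, where the list median of KO SD over WT SD was -0.13 (percentile 29.95). Its corrected median there was 0.14 (percentile 87.6). Potassium channels held 7 higher and 6 lower of 37 (-0.25, percentile 2.58; corrected -0.17, percentile 0.07), with Kcnmb4 at 0.76 (corrected 0.65) and Kcnj4 at 0.98. GABA genes were lower in 8 of 21 (-0.36, percentile 0.895, or 4.08 against lists matched on length; corrected -0.22, percentile 0.065), Gabrb2 most (-1.04). Early genes were higher in 14 of 37 and lower in 1 (0.31, percentile 99.4), with Junb at 1.71 and Per1 at 1.07, but their corrected median was 0.03 (percentile 69.8). Glycolytic genes were higher in 9 of 28 and lower in 1 (0.33, percentile 99.5; corrected 0.13, percentile 99.6), such as Aldoa (0.82). Ribosomal proteins held 22 higher and 3 lower of 51 (0.52, percentile 100; corrected 0.25, percentile 100), with Rps7 (1.86) highest and Rps16 (-2.59) lowest. Interferon genes were lower in 5 of 18 (-0.34, percentile 2.02), such as Gbp3 (-0.80), with a corrected median of -0.06 (percentile 20.4). The mitochondrially encoded transcripts lay at -0.06 (percentile 29.6) and 0.30 after the correction (percentile 100). The medians of the remaining lists lay between percentile 6.47 (thalamus, -0.41) and 97.0 (protein synthesis regulators, 0.27), and Xist differed by -0.30. Of these, the corrected median of oxidative phosphorylation genes was 0.10 (percentile 99.7). The leptomeninges list was at -0.17 (percentile 14.5) and after the correction at -0.29 (percentile 0.01), with 4 of 19 lower.

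The fourth comparison asked how the genotypes differed after sleep deprivation (KO SD over WT SD). Ttr was 4.55 higher in KO SD (4.01 to 5.34 by counting; corrected 4.66), at 581 against 23.8. Genes low in WT SD alone were among the highest, such as the early factor Egr3 (5.33) and Cuedc1 (5.40). Luzp2 (4.49) was lower in WT SD than in WT BL and higher in KO SD than in KO BL. Srp54a, Snurf, Ugt1a6a, Adnp and Slc25a30 were listed at 0 in WT SD, and Irs2 (6.46) and Fam120c (6.34) share exons. Ribosomal and nuclear-encoded respiratory chain transcripts were lower and mitochondrially encoded ones higher, the reverse of their difference between WT SD and WT BL. In all, 2677 genes were higher and 2857 lower, 40.8% of those compared, and after the correction 1958 were higher and 1727 lower. Scaling by total counts turned the balance, with 3140 higher and 2578 lower. This pair has no replicate check and includes WT SD, the library farthest from the rest. The authors' deposited table gave 337 genes as higher and 155 as lower at an adjusted p under 0.05.

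In KO SD, Rps16 (-3.54), Mrpl23 (-3.38) and Eif4ebp3 (-4.02) were lower, and Gp1bb (-4.23), Hist2h2aa1 (-3.35) and Yjefn3 (-3.18) were lower and share exons. Gdf1, Zbtb20, Tom1 and Mier2 were listed at 0 in KO SD. By corrected values and without the ambiguous genes, Psg29 (-2.61), Brip1 (-2.27), Ndufb7 (-2.30), Cst6 (-2.18), the kinesin Kif22 (-2.16) and the glypican Gpc6 (-2.09) were lower. All 51 ribosomal protein genes were lower (median -1.33, percentile 0), and 27 after the correction (-0.60, percentile 0), with Rpl28 at -2.39. Oxidative phosphorylation was lower in 29 of 38 (-1.01, percentile 0; corrected -0.34, percentile 0.365), Ndufa2 most (-2.51). Mitochondrially encoded transcripts were higher in 9 of 13 and lower in 1 (0.96, percentile 100; corrected 0.84, percentile 100), such as mt-Atp8 (3.65). Glutamate genes were higher in 12 of 38 and lower in 2 (0.38, percentile 99.9, or 89.1 against lists matched on length; corrected 0.12, percentile 96.3), and GABA genes in 9 of 21 with 2 lower (0.48, percentile 100; corrected 0.10, percentile 90.2). Endothelial markers were higher in 4 of 10 and lower in 1 (0.52, percentile 98.2, or 95.5 against lists matched on length; corrected 0.33, percentile 96.5), such as Cdh5 (1.29). Red blood cell genes were lower in 4 of 5 (-1.40, percentile 0.10; corrected -0.34, percentile 14.7), Hba-a1 most (-2.37). The medians of the remaining lists lay between percentile 5.82 (inhibitory neurons, -0.40) and 97.2 (calcium genes, 0.18), and Xist was 1.16 higher. Of these lists, the early genes (-0.20, percentile 7.8) lay at percentile 0.59 against lists matched on length. Their corrected median was -0.17 (percentile 7.4). The leptomeninges list was at -0.14 (percentile 21.7) and after the correction at -0.29 (percentile 2.37).

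Genes that differed the same way between genotypes in both conditions were few. The adhesion gene Lrfn1 (1.47 at baseline, 2.20 after sleep deprivation), the transcriptional regulator Sbno2 (1.45 and 2.25), the Nogo receptor homologue Rtn4rl2 (1.29 and 2.12), the palmitoyltransferase Zdhhc22, Kcnj11 (1.23 and 2.73) and Ttr (1.33 and 4.55) were higher in knockout pools. Irs2, Cers1 and Capn15 were higher and share exons, and Snurf was listed at 0 in WT SD. Lower in both were Rps16 (-2.59 and -3.54), Xaf1 (-1.40 and -1.51), Ube3a (-1.07 and -1.07), Tmco5 (-1.05 and -1.03), the phosphodiesterase Pde11a (-0.83 and -1.50) and Lpl (-0.89 and -0.82). Gdf1 and Zbtb20, listed at 0, and Nanp and Itgb3bp, which share exons, were lower too. After the correction the baseline difference was under 1.5-fold for Rtn4rl2 (0.10), Kcnj11 (0.52), Ube3a (-0.46), Pde11a (-0.54) and Lpl (-0.58). By corrected values the death receptor Tnfrsf25 (53.9 against 13.8 and 94.0 against 63.2), the matrix peroxidase Pxdn (0.98 and 1.12), Oprk1 (1.60 and 0.95) and Tmem254c (0.97 and 2.41) were higher in both conditions. So were the pyruvate carrier Mpc1 (1.40 and 1.80), Amy1, Eps8l1, Col5a1 and Tle2, which share exons. Cldn26 (-1.42 and -1.72) and Hfe2 (-0.99 and -1.27) were lower.

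The shared genotype differences numbered 202 higher and 74 lower at deposited values, against 440.0 and 304 by the product of the separate shares. At 2-fold they numbered 56 against 54.2 by chance. Without the filter on the mean they numbered 1518 against 1237, a product lowered by genes without reads, which cannot pass. After the correction they numbered 105 and 79, against 62.4 and 60.0. Across genes, which are not independent replicates, both genotype folds were correlated at -0.27 (Pearson) and -0.38 (Spearman), and at -0.05 and -0.09 after the correction.

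The last comparison asked whether sleep deprivation acted differently in the knockout, as the log2 response in knockout pools minus that in wildtype pools. It was at least 1 in 2254 genes and at most -1 in 2603, and after the correction in 1110 and 754. Scaling by total counts turned the deposited balance, with 2507 and 2347. The rule named genes missing from 1 or more libraries or under a repeated symbol: Srp54a, Snurf, Adnp, Ugt1a6a and Sowahc on the higher side, and Tom1, Hoxd9, Mier2, Eif4ebp3 and Sowahc on the lower. Among genes without these ambiguities, the difference was 6.20 for Htr2a and 4.58 for Egr3, which were far lower after sleep deprivation in wildtype pools (-5.36 and -4.38) and not in knockout pools (0.84 and 0.20). Luzp2 (5.46) was lower in the wildtype and higher in the knockout pair. Mrpl23 (-6.44) and Ndufb7 (-3.74) were higher in the wildtype pair alone. For Nr4a2 the difference was 0.14 and for Nr4a3 -0.27. No residual degrees of freedom were left, so the difference of responses was not tested.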

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

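The tests of position around Kcnma1, of sex and of the marker lists as a whole were set before their results were seen; the tests of GC and length trends, of the leptomeninges and endothelium lists and of the library WT SD were chosen after.

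Opposite responses of the genotypes to sleep deprivation were counted because the differences of response were many. At deposited values 530.0 genes were at least 1.5-fold higher in the wildtype and lower in the knockout pair, against 545 by the product of the separate shares, and 435 went the other way against 527. After the correction these were 44 genes against 134 and 99 against 192. On both scales Junb, which shares exons, was among the first (2.09 and -1.42, corrected 1.28 and -0.72) and Luzp2 among the second (-3.29 and 2.17, corrected -3.57 and 1.75). Whether the responses differed was not tested.

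Genes that differed between genotypes the same way in both conditions might in part reflect strain variants linked to the targeted allele. Of those named above, Xaf1, Pxdn and Oprk1 lie on chromosomes 11, 12 and 1, away from Kcnma1 on chromosome 14. Tmem254c lies on chromosome 14 (26063919 to 26067355), within a window of 20 Mb around Kcnma1. In that window the share of genes that differed the same way was 0.969 times that on other chromosomes (0.196 to 2.92). After the correction it was 1.94 times (0.524 to 5.24, Fisher exact p 0.155). With only 3 and 4 such genes in the window, linkage cannot be told apart from a genotype effect, and neither can unequal sex of the pools: Xist differed by -0.30 at baseline but by 1.16 after sleep deprivation, and Y-linked genes had 4 reads in WT BL, 4 in WT SD, 7 in KO BL and 48.0 in KO SD (0.0808% to 0.361% of Xist), outside the bound set beforehand for both conditions, although Xist was within it at baseline. Of genes higher in knockout pools, 61 unambiguous ones were shared after the correction beside 39.6 by chance (SD 5.74 if genes were independent), more than 2 SD above it. The chance number takes every gene as equally likely to pass 1.5-fold, which was not checked. The excess therefore cannot decide whether GC and length trends were the whole cause. For genes lower in knockout pools the number was 53 beside 43.6 (SD 6.06), within 2 SD, so chance stays open for them. The fitted GC and length trends alone made 0 genes 1.5-fold lower in both conditions and lowered 15 of the 74 shared genes in both. The rank correlation of fold with GC content was 0.80 at baseline and -0.38 after sleep deprivation. With trends of opposite sign, that count of 0 was all but fixed beforehand and is no separate evidence.

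Genes lower in both sleep-deprived pools included those of the leptomeninges and, by corrected values, of red blood cells. Less of both in the dissected tissue may account for part of them. At deposited values 2 of 5 red blood cell genes were lower and 1 higher in the wildtype pair (median -0.53, percentile 6.98). All 5 were lower there only after the correction (-2.14). The marker list farthest from 0 was that of red blood cells in the knockout pair, at -2.10, although at deposited values the trends between libraries moved many lists and this test could hardly have failed; its corrected median was -1.75. The leptomeninges list was at -0.87 after the correction in the genotype with the smaller change (-0.87 in wildtype, where GC and length trends as its whole cause are argued against), but it was chosen from the data and is no independent evidence. A lower share of all vascular cells is argued against in the knockout pair by the endothelium list, at 0.0404 (SD of random lists 0.128), although the list of pericytes, smooth muscle and meninges was at -0.28 there and endothelium at -0.22 in the wildtype pair, where it stays open. Perfusion, dissection and regulation within meningeal cells stay open.

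The library WT SD stood apart from the other 3. After the correction its median deviation from their mean was still 1.63 times the largest of the others (1.60 to 1.67), which argues against GC and length trends as the whole cause. Among genes with no shared exon and no repeated symbol the ratio was 1.61 (1.56 to 1.65), which argues against the division of reads between such genes as the whole cause. Fewer reads are argued against by its 34.9 M estimated reads, beside 27.7 to 42.0 M in the other libraries. A fault in preparing that pool's RNA or library and a true response of those animals stay open, as no second library of the group exists.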

How the results depend on the processing

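The corrections for GC content or length alone, the correction for both in the additive model, list medians and Kcnma1, and the sets without ambiguous genes or WT SD, were chosen after results were seen; the other settings were planned.

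Without a filter on the mean, 12542 genes passed 1.5-fold in wildtype pools after sleep deprivation (6580 with it), 9669 in knockout pools (4418), 8608 between genotypes at baseline (3671) and 11267 after sleep deprivation (5534). The shared changes were 2774 for sleep deprivation (1072), against 1549 by chance, and 1518 for genotype (276), against 1237, and differences of response 10245 (4857). By construction these add genes with few reads, and genes without reads, which cannot pass, lower the numbers given by chance. A 2-fold threshold gave 3411, 986, 657 and 2416 genes, with 202 shared for sleep deprivation, against 127 by chance, and 56 for genotype, against 54.2. The shared genotype differences numbered 517 from a mean of 10, 168 from a mean of 200 and 174 without genes sharing exons or symbols, where fewer genes were compared by construction (1.86% of them, against 2.04%).

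Correction for GC content and length left 1778 genes in knockout pools, 903 at baseline and 3685 between genotypes after sleep deprivation, with 1864 differences of response. Correction for GC content alone left 1839 genes in knockout pools, 927 at baseline and 2704 differences of response. The difference of Kcnma1 became -0.14 at baseline and 1.02 after sleep deprivation. The median of the mitochondrially encoded transcripts in knockout pools went from 0.51 to -0.30, and alone changed sign among the 38 medians at the extremes of their random lists; the cause was not tested. After this correction 97 of all 124 medians kept their sign, 72 were the same within their spread and 51 moved. With total counts 119 were the same, with lists matched on length 110, and with median-of-ratios scaling, the smaller pseudocount or the authors' ratios all 124.

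The additive model in limma called 102 genes for sleep deprivation and 52 for genotype. For sleep deprivation it called 156 from a mean of 10, 52 from a mean of 200, 175 without a filter and 3 after the correction. For genotype it called 21 from a mean of 200 and 1 after the correction. The cause was not tested. Scaling by total counts moved the median of all genes in wildtype pools from -0.04 to -0.21, and the higher share of the additive calls from 32.4% to 22.3%. Other count-based models were not run, as the deposited values are not counts. With the filter on the mean of the libraries other than WT SD, 4387 genes passed in knockout pools and 3645 at baseline. In a window of 10 Mb around Kcnma1 the ratio of shares was 0.857, and 1.94 after the correction. The 20 genes named per comparison kept direction and 1.5-fold in each of the 5 settings tried for them. As they were chosen for the largest folds, this was likely beforehand and says little of smaller differences.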

Other observations

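The naming of further list members was done after the values were seen. By corrected values, several further members of the stress and metabolic lists passed 1.5-fold in both sleep-deprived pairs. The secretory pathway cochaperones Sdf2l1 (1.37 in wildtype, 1.19 in knockout) and Creld2 (1.58 and 1.13) were higher, as was the cell cycle inhibitor Cdkn1a (1.22 and 1.14). The early genes Fosl2 (1.16 and 1.17), an AP-1 subunit, and Sik1 (1.42 and 1.13), a salt-inducible kinase, were higher by near equal amounts. Ppp1r3c, which brings phosphatase to glycogen, was at 1.42 and 1.29, and Pfkfb3, which speeds glycolysis, at 0.79 and 0.86, against the corrected median of their list in knockout pools (-0.24). The cholesterol enzyme Cyp51, which shares exons with another gene, was at 0.90 and 0.62. Cirbp, an RNA-binding protein that rises with cold, was lower in both by corrected values (-1.31 and -0.57), though its knockout value missed 1.5-fold. At deposited values its wildtype difference was under 1.5-fold, so the fall in wildtype pools rests on the correction.

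Lars2, a mitochondrial leucyl-tRNA synthetase, stood at 47230 normalised counts in WT BL, 19270 in WT SD, 53160 in KO BL and 10590 in KO SD. Its corrected difference was -0.82 in wildtype and -2.17 in knockout pools after sleep deprivation. The mitochondrial ribosomal RNA mt-Rnr1 went the other way, from 147300 to 520800 and from 134400 to 337400. The cause was not tested.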
